A study of Mus musculus with 10 samples.

How the data were processed

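RNA was measured with CEL-Seq2 in 4 single-cell libraries, each from 1 plate of 384 wells, and in 6 bulk libraries of sorted TSCs, all from mouse lines on a C57BL/6J background. Each single-cell group (differentiated TSC, TSC, pTSC, blastoid pTSC) has 1 library, and each bulk group (CDX2-high, CDX2-low) has 3. The genome build, the annotation and the program that made the counts are not given in the sources used here, and STAR 2.5.3a is named in the submitters' processing notes. The bulk table, as deposited, holds whole-number counts per gene and library that are not scaled to a common total. The single-cell tables, as deposited, hold counts of transcripts per gene and well, which are treated here as estimated counts. These values are whole numbers, and 93.2% of 3266 values above 300 fall on rounded results of a correction for UMI collisions among 4096 labels, where 85.8% would by chance. Since not all do, it stays open whether such a correction was made. They were used as deposited, with no further rounding. A list of well barcodes without measurements was not used here. The clonal relation between the pTSC library and line pTS1 is not given in the labels.

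Bulk counts were fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, no covariates), and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the root of the F statistic. Gene lists with at least 3 tested members (17 of 23) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, on log-CPM with a prior count of 2. The replicate numbers run on from one bulk group to the other and pair nothing. On simulated counts for this comparison (2944 genes tested, 200 drawn to change), 65 of 91 changed genes were recovered at 2-fold and 87 of 88 at 4-fold, and 11 of 163 calls were false.

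In single cells, wells with at least 2000 UMIs outside mitochondrial genes were kept (no entry among the gene names was taken for a spike-in), which left 1192 cells and dropped 66, 66, 85 and 127 wells in the order differentiated TSC, TSC, pTSC and blastoid pTSC. Of these, 19, 17, 20 and 87 wells held under 200 UMIs. No doublet caller was run on sorted wells, and an alternative left out the 5% of wells with the most UMIs. Counts were summed per library and divided by the total without mitochondrial genes (CPM), and genes with at least 10 counts over both libraries of a comparison were measured. Ratios carry exact conditional binomial intervals at 95%, and list medians intervals from 1000 Poisson draws. These cover counting error only. A count of 0 was set to 3 counts over the library as the limit it allows. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from the same 20 expression bins. Tested on simulated data with 2 libraries drawn from the TSC sums (8558 genes), 95.8% of intervals held the true ratio, a list changed 2-fold lay above all random lists, and an unchanged list lay at percentile 92.8. The simulated counts were Poisson draws, as the intervals assume. They do not show how the intervals hold where the counts of a gene are uneven between cells. Shares of cells were computed after thinning each cell to 2000 UMIs, with exact binomial (Clopper-Pearson) intervals. Shares given as without thinning depend on depth, which differed between libraries. Clusters came from scanpy 1.11.5 (counts scaled to 10000 per cell, log1p, 2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 0.5). Leading genes of a cluster were the 10 with the largest fold among genes with a UMI in at least 25% of its cells, and a cluster was named when at least 3 of them were fixed markers of 1 cell type. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and DESeq2 1.42.0 for an alternative.

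The comparisons, the tests, the cell filter, the rule for named genes and 23 gene lists were fixed before the data were examined. The lists were written from general knowledge of trophoblast biology, and their author knew of the study behind the series, so that polar and mural lists may not be independent of these samples. They are TSC regulators, polar and mural trophectoderm, ectoplacental cone and spongiotrophoblast, trophoblast giant cell, labyrinth and syncytiotrophoblast, epithelial junction and keratin, epiblast and pluripotency, primitive endoderm, fibroblast, FGF and ERK targets, TGF-beta and BMP targets, WNT, YAP, STAT3 and cAMP targets, S phase, G2 and M phase, glycolysis and hypoxia, cholesterol synthesis, immediate early and heat shock, p53 targets and interferon response. In bulk, fewer than 3 members were tested in 6 lists: 2 YAP targets (Cyr61 fell, log2 fold change -1.10, adjusted p = 0.0330 by edgeR, with overlap between the groups, and 0.109 by DESeq2), 2 interferon genes, 1 giant cell gene and 1 cAMP target of which none passed, and no fibroblast gene or WNT target. Named genes in bulk are the 12 with the largest positive and the 12 with the largest negative log2 fold change among genes past the threshold whose groups do not overlap. In single cells they are the 12 with the largest and the 12 with the smallest log2 ratio after adding 10 CPM, among genes with at least 50 CPM and a UMI in at least 10% of cells of the higher library. Everywhere Cdx2, Eomes, Esrrb, Elf5 and Sox2 are added, with up to 4 measured members of each list by size of change. The text gives part of this set. Chosen after the data were seen were the thresholds for naming clusters, the lists that lead each paragraph, the count of lists outside the central 95% of random lists, the setting of 0 to 3 counts, 4 added alternatives, every test of the closing part other than that of the CDX2 lists across cells, and Gdf3, Krt18, Sox3 and Sox21 where named outside the rule. Hand1, and Krt8 and Flt1 in the clusters of blastoid cells, were also named outside it.

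Alternatives were DESeq2, other size factors, no filter on low counts, a test against a 1.5-fold change, limma-trend and leaving out each library in bulk. In single cells they were other minimums for cells (1000 and 5000 UMIs) and genes (50 counts), the mean over cells, TMM scaling, mitochondrial genes in the total, other cluster settings and other thinning. Added later were thinning of all bulk libraries to the smallest total (116659 counts), the pTSC library as the undifferentiated reference, leaving out the pluripotent-like cluster, and leaving out pseudogenes and ribosomal protein genes.

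Gene copies were taken as symbols that end in -ps or -rs with a number, or that start with Gm and a number. Earlier tests of them, 2 in number and made only on the 24 genes with the largest differences (of which 8 were copies), had pointed to plates and pairs of libraries, which the later one left open. They were replaced, after their results were seen, by a test over all eligible copies, because genes selected for a pattern cannot test it. Annotated transcripts were counted in GENCODE vM21, which was chosen here. The test of the CDX2 lists across cells was written down before it was run, but was prompted by looking at clusters of TSCs. Results for some members of the lists are not reported here.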

Results

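Mouse trophoblast stem cells (TSCs), the cultured counterpart of the trophectoderm that surrounds the blastocyst, were profiled in 10 libraries made with CEL-Seq2, a method that counts transcripts by their ends with molecular identifiers (UMIs). Single cells were sorted into plates of 384 wells in 4 libraries, 1 per group. These held TSCs labelled as line F4, TSCs labelled as F4 after 6 days in medium without growth factors (differentiated TSCs), newly derived TSCs grown in LT21 medium (pTSCs), and pTSCs of line pTS1 taken back out of blastoids, which are blastocyst-like structures formed from stem cells (blastoid pTSCs). The other 6 libraries were bulk RNA of TSCs with eGFP knocked in at Cdx2, sorted as CDX2-high (3 libraries) or CDX2-low (3 libraries). Bulk totals were 157588, 257159 and 272030 counts in the CDX2-high libraries and 116659, 138966 and 134978 in the CDX2-low libraries. Wells with at least 2000 UMIs numbered 318 in the differentiated library (3254559 UMIs in all, median 8473 per well), 318 in the TSC library (5388767, median 15091), 299 in the pTSC library (2437481, median 6844) and 257 in the blastoid library (2315931, median 8242).

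The bulk comparison asks which genes go with the level of CDX2, a transcription factor that keeps the trophoblast stem state, within a TSC culture. The Cdx2-eGFP transcript rose to 943 ± 57.9 CPM (SD, n = 3) in CDX2-high libraries from 79.9 ± 41.7 CPM in CDX2-low libraries (log2 fold change 3.53, SE 0.29, adjusted p = 1.31e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gave every adjusted p of this comparison). The entry for untagged Cdx2 held 7 counts over all 6 libraries and was not tested. Among FGF and ERK targets, the pathway that keeps TSCs dividing, 4 of 8 tested members rose and 0 fell. Ccnd1, a cyclin of the G1 phase, rose by 2.51 on the log2 scale (SE 0.46, adjusted p = 0.000968, edgeR), the ERK phosphatase Dusp6 by 1.95 (SE 0.33, adjusted p = 0.000435, edgeR), Myc by 1.64 (adjusted p = 0.0427, edgeR) and Etv4 by 1.51 (adjusted p = 0.0364, edgeR). With DESeq2 the last 2 did not pass (adjusted p = 0.193 and 0.192, DESeq2). Mural trophectoderm is the part of the blastocyst wall away from the inner cell mass. Its markers went the other way: 5 of 7 tested members fell and 0 rose. Among them were the keratin Krt8 (254 ± 37.4 CPM in CDX2-high, 918 ± 120.0 in CDX2-low, SD, n = 3; log2 fold change -1.83, SE 0.22, adjusted p = 7.05e-06, edgeR), Lgals3 (-2.31) and the glucose transporter Slc2a3 (-0.91).

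All 3 tested members of the ectoplacental cone and spongiotrophoblast list fell in CDX2-high libraries, with log2 fold changes of -2.53 for the homeobox gene Rhox9, -1.71 for Rhox6 and -0.92 for the imprinted placental growth regulator Phlda2 (adjusted p = 0.0491, edgeR). With DESeq2 Phlda2 did not pass (adjusted p = 0.187, DESeq2). In the G2 and M phase list 4 of 15 rose and 0 fell, led by Ccnb1 (1.44), a cyclin of mitotic entry, and Ube2c (1.21), which acts in mitotic exit. Polar trophectoderm markers, of the part that touches the inner cell mass, were split: Nat8l (1.69), Ly6a (1.60) and Ddah1 (1.05) rose while Cited1 (-2.00) fell, out of 10 tested. Of 12 epithelial junction and keratin genes, 5 fell, with Krt19 (-1.67) and the desmosomal Dsp (-1.27) beside Krt8, and Perp (1.13) rose. The immediate early genes Jun (-2.45) and Fos (-0.88) fell, out of 6 tested members of their list. Among the 11 tested TSC regulators, Dusp6 rose and Id2 (-1.14), an inhibitor of bHLH factors, fell, and the other 9 did not pass. The core regulators had log2 fold changes of 0.82 for Elf5 (SE 0.28, adjusted p = 0.0898, edgeR), 0.83 for Eomes (SE 0.32, adjusted p = 0.147), 0.88 for Esrrb (SE 0.28, adjusted p = 0.0653) and 0.49 for Sox2 (SE 0.22, adjusted p = 0.227).

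By the set test camera with a preset correlation of 0.01, the mural (adjusted p = 2.26e-08), ectoplacental (adjusted p = 3.92e-05), epithelial (adjusted p = 0.00146) and immediate early (adjusted p = 0.0239) lists were lower in CDX2-high libraries. The G2 and M phase (adjusted p = 1.94e-05), FGF and ERK (adjusted p = 0.00129) and polar (adjusted p = 0.0157) lists were higher. None of these 7 calls held with an estimated correlation: adjusted p = 0.0564 with an estimated correlation for the mural list, 0.0897 for the ectoplacental, epithelial, G2 and M phase and FGF and ERK lists, 0.125 for the polar list and 0.139 for the immediate early list. By the rotation test fry all 7 lists passed (adjusted p from 0.00516 to 0.0156 by fry), and so did the primitive endoderm list (adjusted p = 0.0364 by fry). Adjusted over the list alone, 0 rose and 7 fell in the mural list, 0 and 3 in the ectoplacental list, and 8 and 0 in the G2 and M phase list. They were 5 and 1 among FGF and ERK targets, 6 and 2 in the polar list, 1 and 5 in the epithelial list, 0 and 2 in the immediate early list, and 5 and 2 among TSC regulators (camera adjusted p = 0.0691). The mural and epithelial lists share keratins, so their counts are not independent. The other 9 lists with at least 3 tested members did not pass camera. The S phase list had 1 member up of 10 tested (Rrm2, 0.82), TGF-beta and BMP targets 1 up of 4 (Tgif1, 1.52), STAT3 targets 1 down of 5 (Socs3, -1.89), the glycolysis and hypoxia list 1 down of 7 (Slc2a1, -0.90) and the labyrinth list 1 down of 3 (Cebpb, -1.51). No member passed among 10 cholesterol synthesis genes, 5 p53 targets, 5 primitive endoderm and 4 epiblast and pluripotency genes. Adjusted over the list alone, these counts were the same except in the primitive endoderm list, where 1 rose and 3 fell, and among TGF-beta and BMP targets, where 1 rose and 2 fell.

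Of 17793 genes in the table, 3006 were tested and 177 passed, 93 higher and 84 lower in CDX2-high libraries. Beside the reporter, the largest increases with no overlap between groups were in Zic2 (log2 fold change 3.34, SE 0.41), a transcription factor, and Inpp1 (2.90). Next came Duoxa2 (2.67), a maturation factor of the dual oxidase Duox2, Ccnd1 (2.51), Pth1r (2.27), the zinc transporter Slc30a3 (2.26) and Rin2 (2.22). The transcription factor Sox3 (2.20), Upp1 (2.18), the gelatinase Mmp9 (1.99) and Cldn26 (1.98) followed. The largest decreases were in the X-linked homeobox gene Rhox13 (-3.93, SE 0.61), Igfbp2 (-3.17), which binds insulin-like growth factors, the galectin Lgals9 (-3.07), Fxyd6 (-2.65), Syt13 (-2.55), Marcks (-2.55), Rhox9, Jun, its partner Fosl2 (-2.45), Lgals3, Txnip (-2.20) and Tns4 (-2.05). Of the 177 genes, 175 had all 3 libraries of one group above all 3 of the other, as did 687 of the 3006 tested (22.9%, where 10% is the share by chance). DESeq2 called 88 of these genes and, of those named, not Sox3, Ddah1, Phlda2, Cebpb, Krt19, Dsp, Myc, Etv4, Tgif1, Rrm2, Fos or Cyr61, and 95, 102 and 81 genes passed without CDX2-high library 37, 38 and 39. All CDX2-high libraries were deeper than all CDX2-low ones, and 109 genes passed after thinning to the smallest total. The p-values measure only the spread between these 6 libraries, part of which can be technical.

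**Figure D1:**
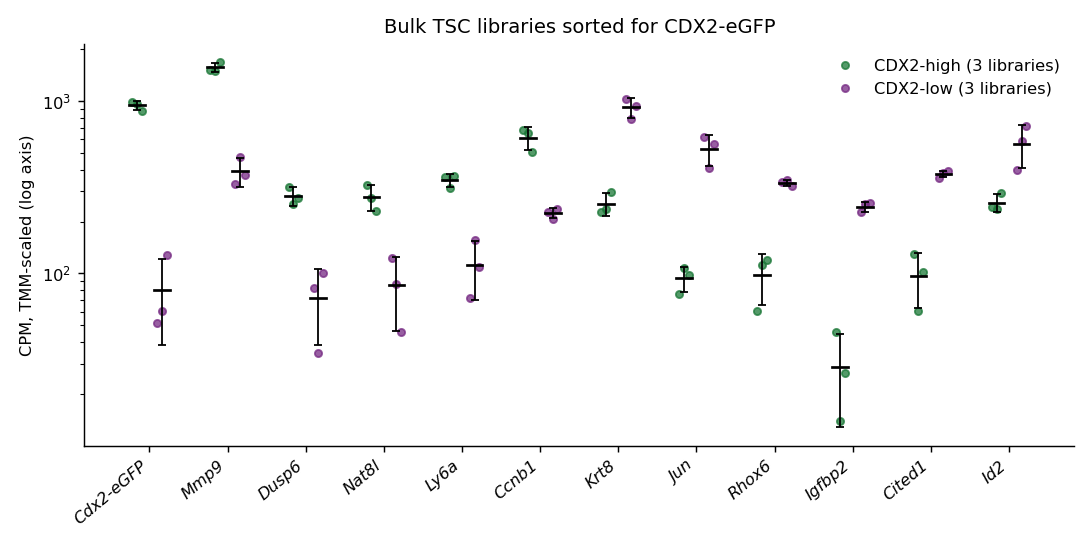
TMM-scaled CPM (log axis) of 12 genes in the 3 CDX2-high and 3 CDX2-low bulk libraries. Points are libraries, black bars the mean and whiskers 1 SD. The Cdx2-eGFP transcript averaged 943 CPM against 79.9, and Krt8 254 CPM against 918.

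The single-cell libraries have no replicates, so their values carry no test, and all intervals below are 95% intervals for counting error only. A gene counts as higher or lower where its CPM differed at least 2-fold, which is a rule of size. A list's median log2 ratio is placed among those of 10000 random lists of like size and expression, and a list outside the central 95% of them is called outside its random range. Levels of different genes cannot be compared with each other in these libraries: relative to bulk CDX2-high libraries, the median log2 ratio of the TSC sums was 0.79 for 194 genes with 1 annotated transcript and -2.41 for 2162 genes with 5 or more.

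Differentiated TSCs against TSCs asks what changes when the growth factors are withdrawn. The stem cell programme was lower in the differentiated library: 13 of 17 TSC regulators lay at least 2-fold lower and 0 higher (median log2 ratio -1.66, interval -2.18 to -1.54, below all 10000 random lists). Cdx2 was at 2.46 CPM against 49.9 (20.3-fold lower, 10.2 to 47.5). Eomes, a T-box factor of the trophoblast lineage, was at 119 against 377 (3.16-fold, 2.83 to 3.53), Sox2 at 297 against 760 (2.56-fold, 2.38 to 2.75), and Elf5 at 2 UMIs against 204 (61.6-fold, 16.8 to 512), while Esrrb had only 3 and 11 UMIs. Polar trophectoderm genes were lower too (8 of 11, 0 higher, median -2.28, interval -2.72 to -1.87), with Nat8l 23.1-fold (19.1 to 28.1), Ddah1 10.6-fold and the X-linked homeobox gene Rhox5 6.62-fold lower. Markers of differentiated trophoblast were higher in part. Of 6 measured ectoplacental genes 4 were higher and 1 lower (median 1.18). The kinase Nrk was at 1517 CPM against 200.2 (7.57-fold, 7.09 to 8.10) and Rhox6 at 1743 against 564, while Ascl2 had 0 UMIs against 19. Nrk, Rhox6 and Rhox9, all higher, are X-linked, and these libraries also differed in sex-linked RNAs, as given below. Only 6 of 21 listed trophoblast giant cell genes were measured, of which 4 were higher and 1 lower (median 2.02). The serpin Serpinb9e was 9.22-fold and Bhlhe40 6.77-fold higher, while Hand1 was lower, at 3 UMIs against 14. Ctsj, also counted as higher, had 71 UMIs in 1.26% of differentiated cells. Bhlhe40 was not higher than in the pTSC library (log2 ratio -0.0487). Of 10 labyrinth genes 4 were higher and 2 lower (median 0.95), with Hsd11b2, which inactivates glucocorticoids, 31.5-fold (16.2 to 70.0) and the transcription factor Dlx3 3.86-fold higher. Without thinning, a UMI of Hsd11b2 was found in 9.12%, of Serpinb9e in 22.96% and of Dlx3 in 29.2% of differentiated cells. Others of these RNAs were found in most of them, Nrk in 85.2%, Rhox6 in 96.5% and Bhlhe40 in 63.8%. Serpinb9e and Hsd11b2 were among the leading genes of a cluster with 21.4% of that library.

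Mural trophectoderm markers were mixed in this comparison (5 of 15 higher, 2 lower, median 0.10, inside the random range), although Krt8 stood at 2224 CPM against 350 (6.36-fold, 6.04 to 6.69), the VEGF receptor Flt1 at 552 against 103 (5.38-fold) and the iodide transporter Slc5a5 9.30-fold higher. Cell cycle genes were lower in the differentiated library, 10 of 15 in the G2 and M phase list (median -1.13; Plk1 4.31-fold and Birc5 4.86-fold lower) and 2 of 12 in the S phase list (median -0.83; Rrm2 2.01-fold lower). Cholesterol synthesis genes were lower (6 of 14, median -0.94), with the sterol sensor protein Insig1 11.3-fold (9.43 to 13.5) and Msmo1 5.29-fold lower. Of 13 glycolysis and hypoxia genes 7 were lower and 0 higher (median -1.01; Pfkl 3.60-fold, Slc2a1 2.80-fold). That median is the ratio of Ldha, at 3 UMIs against 10, so its size rests on few counts. The better counted Tpi1 (518 against 679 CPM) and Bnip3 (275 against 263 CPM) were within 2-fold. TGF-beta and BMP targets were higher (7 of 12, median 1.09), with Nodal 4.14-fold higher and the BMP inhibitor Smad6 4.93-fold lower. Of 4 measured WNT targets 2 were higher (median 1.19), Dkk1 4.70-fold and Lgr5 at 19 UMIs against 1. Tcf7 (58.1 against 57.9 CPM) and Znrf3 (46.4 against 41.8 CPM) were within 2-fold. Also higher were p53 targets (4 of 10, 1 lower, median 0.77; Ccng1 2.45-fold higher, Bax 2.31-fold lower) and immediate early and heat shock genes (4 of 9, 1 lower, median 0.81; Jun 3.55-fold, Hspa1b 3.84-fold). Interferon response genes were lower (7 of 10, median -1.60; Isg15 19.2-fold). STAT3 targets went both ways (2 of 7 lower, 1 higher, median -0.86, interval -1.09 to 0.17; Socs3 2.15-fold lower, Pim1 2.08-fold higher), and their median was 0.61 with a gene minimum of 50 counts. FGF and ERK targets (4 of 10 lower, 1 higher, median -0.57), epithelial genes (median -0.05), epiblast genes (median 0.91; Klf2 4.09-fold higher), primitive endoderm genes (median 0.35), YAP targets (median -0.15), cAMP targets (median 0.90) and 3 fibroblast genes (median -0.56) lay inside their random ranges.

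Outside the lists, the pantetheinase Vnn1 (29.2-fold), Timp2 (14.6-fold), the small heat shock protein Cryab (10.6-fold) and the protease inhibitor Serpine2 (10.6-fold) were among the genes with the largest excess in the differentiated library. The imprinted RNAs H19 (37 UMIs against 33921) and Meg3 (7 against 888) and the X-inactivation RNA Xist (14 against 1515) were among those with the largest deficit. The 5 Y-linked genes examined had 226 UMIs in the differentiated library, 0 in the TSC library, 1 in the pTSC library and 2 in the blastoid library. The differentiated library thus differed from the TSC library in sex-linked RNAs as well as in medium. With the pTSC library in place of the TSC library as the undifferentiated one, TSC regulators (median -2.28) stayed lower, while the medians of TGF-beta and BMP targets (-0.42) and interferon genes (0.68) changed sign, as did the log2 ratios of Isg15 (2.34), Meg3 (2.39, from 7 UMIs and 1) and Bhlhe40.

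The comparison of pTSCs with TSCs sets a new line in LT21 medium against line F4 in Tx medium. FGF and ERK targets were higher in pTSCs: 7 of 10 lay at least 2-fold higher and 0 lower (median log2 ratio 1.57, interval 1.23 to 1.69, above all 10000 random lists). The feedback inhibitors Spry4 (182 CPM against 48.1, 3.78-fold, 3.24 to 4.43) and Spry2 (3.95-fold), Dusp6 (321 against 131, 2.45-fold) and Ccnd1 (4.88-fold) were among them. Interferon response genes were lower in pTSCs (6 of 9, median -3.42, interval -3.66 to -2.48), with the ubiquitin-like Isg15 at 1.64 CPM against 159 (97.1-fold lower, 37.8 to 357), Oas1a 14.8-fold lower and Usp18 at 0 UMIs against 206 (at least 31.1-fold lower, taking 3 counts as the limit of a 0). TSC regulators as a list did not stand apart (4 of 17 higher, 1 lower, median -0.17): Cdx2 was at 54.6 against 49.9 CPM (1.09-fold, 0.881 to 1.35), Eomes 1.54-fold higher, Sox2 1.33-fold and Elf5 2.20-fold lower, and Esrrb had 17 and 11 UMIs. Markers of differentiated trophoblast were lower in pTSCs, with 4 of 6 ectoplacental genes (median -1.35; Phlda2 at 55.0 CPM against 755, 13.7-fold, and Nrk 4.40-fold), 4 of 6 giant cell genes (median -1.89, 3 of them at 0 UMIs in pTSCs, among them Serpinb9e; Bhlhe40 was 7.01-fold higher) and 5 of 9 labyrinth genes (median -1.19; Dlx3 4.58-fold and the gap junction gene Gjb2 111-fold lower). Without thinning, a UMI of Gjb2 was found in 10.1%, of Dlx3 in 11.9% and of Serpinb9e in 4.09% of TSCs, but of Phlda2 in 89.6% and of Nrk in 52.8%.

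Polar trophectoderm genes were higher (4 of 12, 1 lower, median 0.49), with the glutathione transferase Gsto1 at 10333 CPM against 1034 (9.99-fold, 9.71 to 10.3) and the oxidase Duox2 3.94-fold higher. Epithelial genes were higher too (3 of 15, 1 lower, median 0.50; Perp 3.22-fold, Krt8 2.52-fold, Cldn3 2.22-fold). TGF-beta and BMP targets (7 of 13, median 1.04; Lefty2 43.5-fold, 14.2 to 217) and 2 of 4 measured fibroblast genes (median 2.01; Thy1 9.14-fold, Col5a2 with 21 UMIs against 2) were also higher. Glycolysis and hypoxia genes were lower (5 of 13, 1 higher, median -0.73; Bnip3 2.39-fold, Tpi1 2.23-fold). Their median is the ratio of Pgk1, at 3 UMIs against 11, so its size rests on few counts. Mural genes (median 0.30; Flt1 3.87-fold higher, Ndrg1 4.03-fold lower), cholesterol synthesis (median 0.30; Cyp51 2.31-fold higher), S phase (median 0.14, with Rrm2 4.17-fold higher) and G2 and M phase (median -0.03) lay inside their random ranges. Largest by the size rule were Baiap2l1 (47.1-fold), the homeobox gene Hoxc9 (58.1-fold, 36.8 to 97.3), fibronectin Fn1 (28.2-fold) and the ERK-responsive factor Ets1 (20.03-fold) on the higher side. On the lower side were the interferon-induced Rtp4 (170-fold, 58.0 to 826) and Gbp7 (69.5-fold). Of the 24 genes that this rule selected, 9 were pseudogenes, predicted genes or ribosomal protein genes whose reads can be shared with copies, and 8 of 24 were such in the comparison of differentiated with undifferentiated cells. They are left unnamed as uncertain. Baiap2l1 is uncertain as well: it was at 33.2 and 38.7 CPM in the TSC and differentiated libraries and at 1566 and 1484 CPM in the pTSC and blastoid libraries. For it, a difference of line or medium and one of counting between these pairs cannot be told apart.

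Blastoid pTSCs against pTSCs asks how trophoblast cells taken from blastoids differ from pTSCs in culture. The labels do not tie the pTSC library to line pTS1, so line and plate are not separated from the blastoid. FGF and ERK targets were lower in the blastoid library: 8 of 10 lay at least 2-fold lower and 0 higher (median log2 ratio -2.44, interval -2.81 to -2.24, below all 10000 random lists). Spry4 was at 12.95 CPM against 182 (14.0-fold lower, 9.69 to 21.04), Dusp6 at 29.8 against 321 (10.8-fold, 8.41 to 14.0) and Phlda1 7.94-fold lower. TSC regulators (4 of 17 lower, 0 higher, median -0.76) and polar trophectoderm genes (5 of 12 lower, 0 higher, median -0.93) were lower too. Eomes was at 300.1 CPM against 581 (1.94-fold, 1.77 to 2.12), Cdx2 at 32.8 against 54.6 (1.66-fold, 1.25 to 2.23). Sox2 was 1.73-fold, Nat8l 5.48-fold, Gsto1 3.49-fold and Elf5 1.29-fold (0.790 to 2.12) lower. Mural trophectoderm genes were higher (5 of 15, 2 lower, median 0.80, interval 0.73 to 0.96, above all random lists), with the stress-induced Ndrg1 at 751 CPM against 84.9 (8.85-fold, 7.66 to 10.3), Dkkl1 5.92-fold and the water channel Aqp3 5.26-fold higher. All 6 measured ectoplacental genes were higher (median 2.32), Phlda2 14.8-fold (12.4 to 17.7), Nrk 6.86-fold and Sct, which encodes the hormone secretin, 5.95-fold. Of 7 labyrinth genes 4 were higher (median 1.49; Dlx3 12.5-fold, Gjb2 34.7-fold, 11.5 to 171). Of 6 giant cell genes 2 were higher and 1 lower (median 0.92), with Serpinb9e at 162 UMIs against 0 (at least 56.8-fold) and Bhlhe40 3.19-fold lower. Without thinning, a UMI of Gjb2 was found in 4.67%, of Dlx3 in 9.73% and of Serpinb9e in 5.45% of blastoid pTSCs. For Phlda2 the share was 61.1%, for Nrk 33.9% and for Sct 22.2%. The library pools 2 clusters of 101 and 133 cells, and part of these differences lay in the smaller one. Nrk was at 695 CPM in the smaller and 23.7 in the larger cluster, against 45.5 in pTSCs, while Phlda2 was above the pTSC level in both (1624 and 235 CPM). Eomes was at 43.4 and 519 CPM, Cdx2 at 17.98 and 48.1 and Sox2 at 15.9 and 490 CPM in the same order, so for these genes the larger cluster lay nearer to pTSCs (573 CPM for Sox2). Dusp6 was below the pTSC level in both (9.52 and 43.2 CPM). Mural genes differed in this respect. Krt8 (3156 and 669 CPM, against 882 in pTSCs) and Flt1 (1369 and 131, against 397) were below the pTSC level in the larger cluster. Ndrg1 (1305 and 387 CPM) and Dkkl1 (257 and 58.7 CPM, against 24.2 in pTSCs) were above the pTSC level in both.

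Cholesterol synthesis genes were lower in blastoid pTSCs (12 of 14, 0 higher, median -1.63), with Cyp51, a demethylase of lanosterol, at 229 CPM against 887 (3.87-fold, 3.52 to 4.26) and Fdft1 3.55-fold lower. YAP targets were lower as well (4 of 7, median -1.72; Cyr61 8.74-fold, 7.42 to 10.4, and Ajuba 3.29-fold). So were immediate early genes (5 of 9 lower, 1 higher, median -1.14; Fos 3.83-fold and Zfp36 2.90-fold lower, Hspa1b 2.38-fold higher), TGF-beta and BMP targets (5 of 12 lower, 1 higher, median -0.79; Msx2 3.14-fold and Smad6 3.33-fold lower, Id3 3.49-fold higher) and 3 of 4 fibroblast genes (median -2.07). Of 7 STAT3 targets 2 were lower and 0 higher (median -0.73, interval -1.06 to 0.07, and 0.0488 as a mean over cells), which leaves their direction open. Epithelial genes were higher (3 of 15, 1 lower, median 0.50; Krt7 2.25-fold and Dsp 2.07-fold higher, Perp 2.55-fold lower). Glycolysis and hypoxia genes (median 0.36; Bnip3 2.75-fold higher), S phase (median -0.14), G2 and M phase (median 0.0029), p53 targets (median 0.27), interferon genes (median 0.18), WNT targets (median 0.64), cAMP targets (median -0.08) and primitive endoderm genes (median 0.07) lay inside their random ranges. Largest by the size rule were also the vitamin D receptor Vdr (16.6-fold), the fatty acid importer Cpt1a (9.07-fold) and Arid3a (5.54-fold) on the higher side. On the lower side were Sox3 (12.99-fold), Foxq1 (9.28-fold) and Hoxc9 (6.49-fold). The epiblast and pluripotency list was higher (7 of 10, median 2.52; Tdh 76.8-fold, 13.4 to 3076, and Fgf4 23.7-fold), and without a cluster of 18 cells its median was -0.46.

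**Figure D2:**
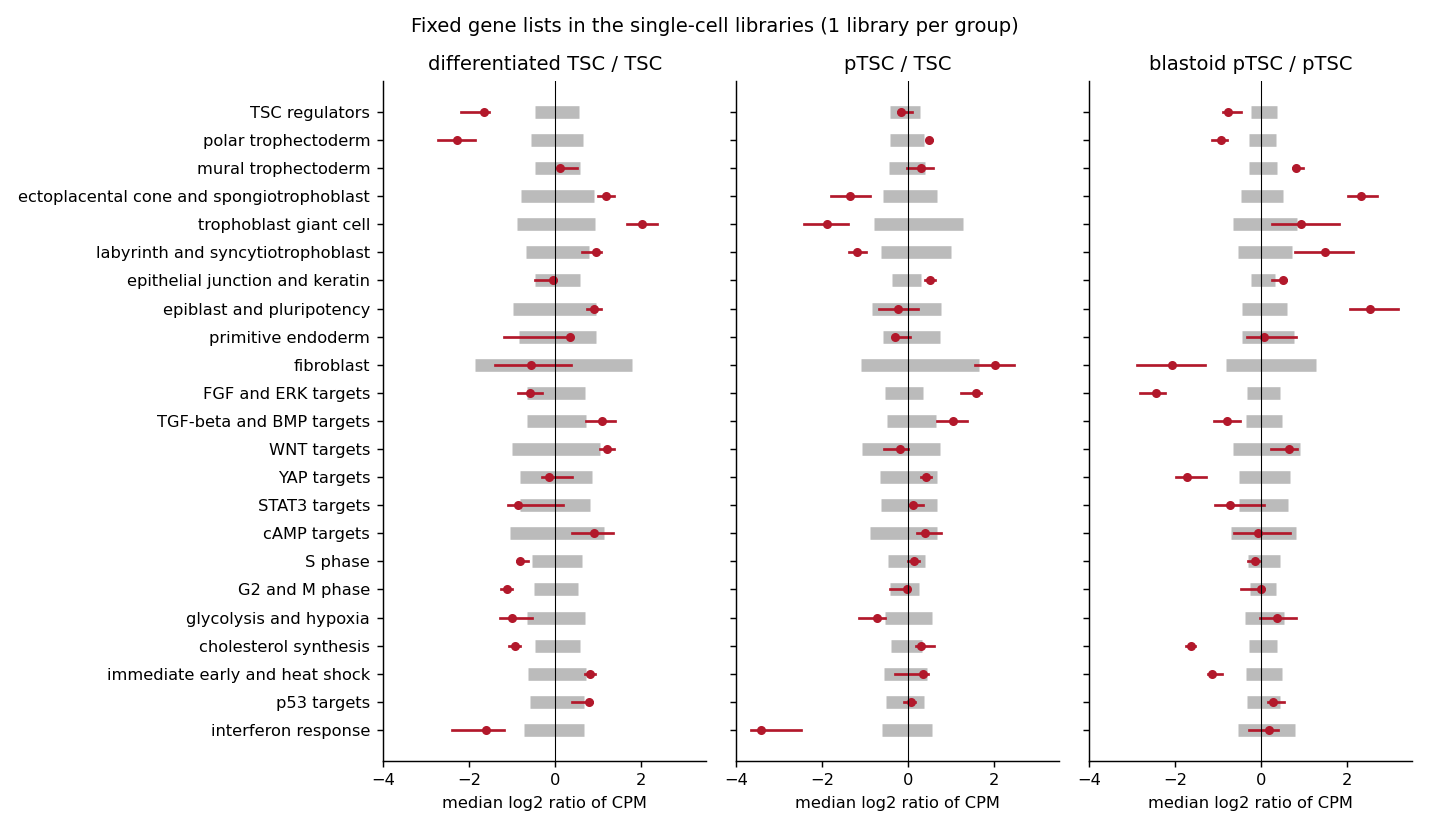
Median log2 ratio of CPM (horizontal axis) of the 23 gene lists in the 3 single-cell comparisons. Points are medians, red lines their 95% intervals for counting error, and grey bars the central 95% of 10000 random lists. FGF and ERK targets stand at 1.57 in pTSC over TSC and at -2.44 in blastoid pTSC over pTSC. Both ratios use the same pTSC library.

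**Figure D3:**
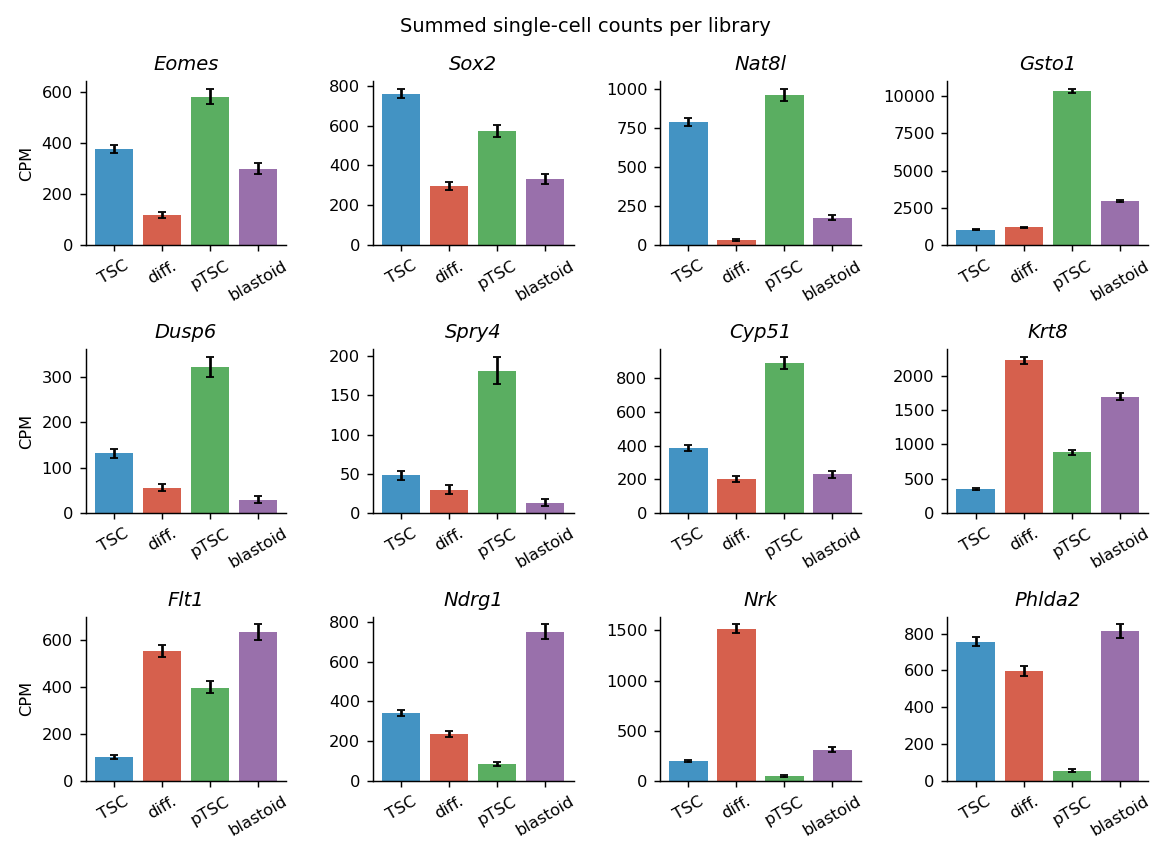
CPM of 12 genes in the summed counts of the 4 single-cell libraries (1 library per group). Bars are levels and whiskers 95% intervals for counting error only. Dusp6 stands at 321 CPM in pTSC and 29.8 in blastoid pTSC, and Krt8 at 350 CPM in TSC and 2224 in differentiated TSC.

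Those 18 cells formed a cluster of their own among the 1192 cells of all 4 libraries. It held 7.004% of the blastoid library (exact binomial interval 4.203 to 10.8%) and 0 cells of the others, with an upper limit of 1.23% of pTSCs, and its leading genes included the pluripotency genes Tdh, Tdgf1, Fgf4, Dppa5a and Gdf3. It was called pluripotent-like from markers fixed before the data were examined, by a naming threshold chosen afterwards. Tdgf1, a coreceptor of Nodal, had a UMI in 16 of the 18 cells and in 1 of the other 239. The 18 cells were grouped by their expression and Tdgf1 was a leading gene, so that split arises in part by construction. The trophoblast keratin Krt18 was at 126 CPM in these cells against 4287 CPM in the other blastoid cells. Sox2 was at 1381 CPM in the 18 cells and at 282 CPM in the others, against 573 CPM in pTSCs. The 18 cells thus raise the Sox2 level given above for the whole blastoid library. The other 6 clusters were not named, and each held cells mostly of 1 library. Differentiated cells lay mainly in 2 of them (246 and 68 cells), as did blastoid cells (101 and 133).

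After thinning each cell to 2000 UMIs, a UMI of Eomes was found in 15.4% of differentiated cells (11.6 to 19.9%), 44.7% of TSCs (39.1 to 50.3%), 63.5% of pTSCs (57.8 to 69.0%) and 35.4% of blastoid pTSCs (29.6 to 41.6%). Krt8 was found in 87.4, 40.3, 61.9 and 72.4% of cells in the same order. Without thinning the shares were 32.4, 81.4, 86.3 and 53.3% for Eomes and 97.2, 80.5, 89.0 and 89.1% for Krt8. Wells with under 200 UMIs, which serve as background, had a UMI of the abundant Krt18 in 3 of 19, 1 of 17, 3 of 20 and 15 of 87 wells in the same order, at medians of 97, 45, 116.5 and 35 UMIs. Background differed between genes and libraries: Gsto1 had a UMI in 1 of 19, 1 of 17, 12 of 20 and 16 of 87 of these wells, and H19 in 0 of 19, 6 of 17, 10 of 20 and 34 of 87.

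The genes called in bulk were then followed in the single-cell comparisons, to see whether genes that go with CDX2 level also differ between the cell states. The CDX2-high genes were lower in differentiated TSCs than in TSCs (median log2 ratio -0.94, interval -1.08 to -0.81, 71 measured, 35 lower and 5 higher, below all 10000 random lists), while the CDX2-low genes went both ways (16 of 74 measured higher and 15 lower, median -0.04, percentile 21.5). In pTSCs against TSCs the CDX2-high genes had a median of 0.20 (interval 0.03 to 0.30, percentile 99.6) and the CDX2-low genes one of -0.46 (below all random lists). In blastoid pTSCs against pTSCs the order turned: CDX2-high genes such as Sox3, Dusp6 and Nat8l were lower as a set (median -0.55, interval -0.67 to -0.44, 24 of 72 lower and 1 higher) and CDX2-low genes such as Phlda2 higher (median 0.63, interval 0.51 to 0.72, 20 of 68 higher and 4 lower, above all random lists). The same pTSC library enters this comparison and the one with TSCs. A trait of that library alone would thus give opposite signs. Phlda2 was at 755 CPM in TSCs, 55.0 in pTSCs and 812 in blastoid pTSCs. Sox3 (67.5, 258 and 19.9 CPM in the same order), Dusp6 (131, 321 and 29.8) and Nat8l (788, 960 and 175) were lowest in blastoid pTSCs.

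**Figure D4:**
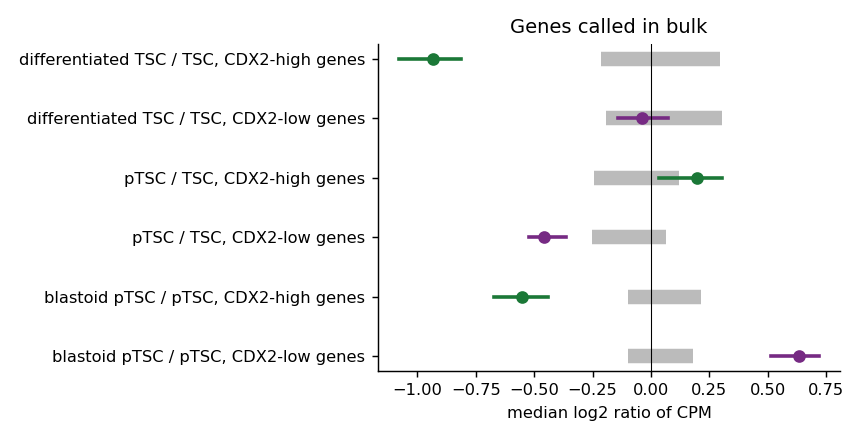
Median log2 ratio of CPM (horizontal axis), in each single-cell comparison, of the genes called higher in CDX2-high or in CDX2-low bulk libraries. Points are medians, coloured lines 95% intervals for counting error and grey bars the central 95% of 10000 random lists. The CDX2-high genes stand at -0.94 in differentiated TSC over TSC.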

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

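No test was chosen for the results of this part, which stand as values. The share of UMIs from mitochondrial genes, which lie outside the comparisons of the report, was 22.9% in the differentiated library (exact binomial interval 22.86 to 22.94%) against 13.8% in the TSC library. It was 19.3% in the blastoid library (interval 19.24 to 19.33%) against 15.1% in the pTSC library. Both drew attention because the level lay above that of the library each was compared with, and the intervals cover counting error only. The median well held 22.4% in the differentiated and 13.1% in the TSC library, and 19.1% in the blastoid and 14.7% in the pTSC library. No explanation was tested.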

How the results depend on the processing

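Chosen after the results were seen were the splits and the thinning of the bulk libraries, the pTSC library as reference, and leaving out the pluripotent-like cells or the gene copies. The bulk count of 177 became 88 with DESeq2, 46 against a 1.5-fold change (a stricter hypothesis) and 109 after thinning to the smallest total. Leaving out 1 library gave 81 to 189 genes: 95, 102 and 81 without CDX2-high libraries 37, 38 and 39, and 164 to 189 without a CDX2-low library. It stayed within 1.5 times the main count under RLE factors (175), library totals (174), limma-trend (135) and no filter (223, of which 136 higher, with 151 shared). Of the 10 splits of the 6 libraries into 3 and 3, the real one called 177 genes and the highest other 0, and 1 of 10 reached the real count. These are too few splits for a share under 0.05. Every other split also mixed CDX2-high and CDX2-low libraries in both groups. That adds the difference between them to the spread, so their low counts decide little. With an estimated correlation, 0 lists passed in place of 7. Among values of named bulk genes under the alternatives, 577 kept direction and side of the threshold, 102 kept direction but no longer passed, and 4 came to pass.

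In single cells, 173 list medians of pTSC over TSC, 173 of blastoid pTSC over pTSC and 149 of differentiated TSC over TSC stayed within their counting intervals, and 10, 8 and 31 moved beyond them. The sign turned for 0, 2 and 3 more, which are given below. The STAT3 median changed to 0.61 in differentiated cells with a gene minimum of 50 counts, where fewer members were measured, and to 0.0488 in blastoid cells as a mean over cells, where the cause was not tested. Against the pTSC library, the differentiated library gave -2.28 for TSC regulators, -0.42 for TGF-beta and BMP targets, 0.68 for interferon genes, -0.0487 for Bhlhe40, 2.34 for Isg15, 2.39 for Meg3 and -0.41 for Phlda1. The mural median of blastoid cells was 0.72 with TMM and 0.73 with mitochondrial genes in the total. Without the pluripotent-like cells the epiblast median was -0.46, since those cells carry its genes. Clusters numbered 7, 11 at resolution 1.0 and 9 with 10 components. At 5000 UMIs the Eomes shares in differentiated cells, TSCs, pTSCs and blastoid cells were 25.7, 63.6, 87.0 and 46.6% and those of Krt8 97.2, 58.7, 87.5 and 91.7%. Without thinning they were 32.4, 81.4, 86.3 and 53.3%, and 97.2, 80.5, 89.0 and 89.1%. Pseudocounts and filters for normalized values were not run, since the bulk table holds counts. Esrrb had only 3 to 17 UMIs per library, against 296.6 CPM in CDX2-high bulk libraries, so its single-cell ratios decide little.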

Other observations

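The test of the CDX2 lists across single cells was written down before it was run, though prompted by clusters of TSCs seen earlier, while the tests on sex-linked RNAs, on gene copies and on annotated transcripts, and the look at blastoid clusters, were chosen afterwards. Blastoid pTSCs fell mainly into 2 clusters, of 101 and 133 cells with median depths of 8269 and 8579 UMIs. Relative to the larger, the smaller was lower in TSC regulators (12 of 16 members, median log2 ratio -2.04; Eomes at 43.4 against 519 CPM), polar trophectoderm genes (9 of 11, median -2.13) and FGF and ERK targets (8 of 9, median -2.33). It was higher in mural trophectoderm genes (9 of 13, median 1.499; Flt1 at 1369 against 131 CPM), ectoplacental genes (6 of 6, median 2.64; Nrk 695 against 23.7) and labyrinth genes (6 of 7, median 1.79). The G2 and M phase list was lower (8 of 14, median -1.04). The clusters were made from the expression of the same genes, so that some differences arise by construction, and these values come from 1 library.

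The genes called higher in CDX2-high and those called higher in CDX2-low bulk libraries may mark opposite ends of a range among the cells of 1 culture. Across the 318 TSCs, at 2000 UMIs each, the UMIs of both lists were related with Spearman's rho of -0.542, where the central 95% of 1000 pairs of random lists of like expression ran from -0.128 to 0.177. The same relation gave -0.332 in differentiated cells, -0.269 in pTSCs and -0.556 in blastoid pTSCs, each below all random pairs. The random lists were matched on expression and not on how their genes vary together. The range thus cannot tell a relation to CDX2 from other variation that the listed genes share. In the smaller blastoid cluster relative to the larger, the CDX2-high genes had a median log2 ratio of -1.11 and the CDX2-low genes one of 0.37. The blastoid value thus follows that split in part. Cells of 1 library are not replicates, and the bulk libraries hold Y-linked RNA that the TSC library lacks, so such a range among cells remains a hypothesis.

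Sex-linked RNAs set the differentiated library apart from the TSC library, although both are labelled line F4. The differentiated library held 226 UMIs of 5 Y-linked genes and the TSC library 0, as would be seen if these libraries came from cells of different lines, one XY and one XX. A share of male cells mixed into a female culture would leave Xist in the other cells, but among 179 differentiated cells without a Y-linked UMI 0.559% had an Xist UMI, against 39.6% of TSCs. For H19 a difference between lines and a loss in 6 days of differentiation cannot be told apart: the undifferentiated bulk libraries, which hold 201 counts of the Y-linked Ddx3y, had H19 at 18.6 CPM, which leaves both open. An effect of the medium on the other genes of that comparison was not separated from one of the line.

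Pseudogene copies stood out in the pTSC against TSC comparison. Over all 114 eligible pseudogenes and predicted genes, the median log2 ratio lay 1.49 (interval 1.34 to 1.76) above that of other genes, and 1.80 above it in blastoid pTSCs against differentiated TSCs. Within pairs of libraries with like titles it differed by 0.0033 in blastoid against pTSC (interval -0.07 to 0.13), but by -0.39 in differentiated against TSC (interval -1.03 to 0.20), where 50.8% of copies and 21.4% of other genes lay at least 2-fold apart. A difference between the pairs in sequencing or counting and a difference of line or medium cannot be told apart, because both change with the pair and copies also differed inside 1 pair. This test replaced 2 earlier ones on the 24 leading genes.

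Genes with many annotated transcripts were low in the single-cell sums relative to bulk, with a median log2 ratio 3.20 lower for 5 or more transcripts than for 1 (difference -3.20, interval -3.54 to -2.87, over protein-coding genes at 50 CPM or more in bulk, 96.4% of 3598 symbols matched to the annotation). Gapdh, for example, had 15.2 CPM in TSC single cells and 1628 CPM over the bulk libraries. Another expression programme in the single-cell line had been predicted, after the data were seen, to follow the gene and not its number of transcripts, which was not met. This cannot decide, because a programme was not shown to be unrelated to transcript number and the genes were chosen by their bulk level. A loss of reads that fit several transcripts of a gene in the single-cell counting may account for the difference, and the annotation used by the submitters remains unknown.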
